A study of Mus musculus with 44 samples.

How the data were processed

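DNA methylation was measured by reduced representation bisulfite sequencing (RRBS), which enriches CpG-dense fragments of the genome before bisulfite conversion and reads, at each cytosine, the share of molecules that are methylated. The 44 libraries came from whole blood, hippocampus and frontal cortex of adult male C57BL/6J mice, and per the labels' protocols each was made from 100 ng of genomic DNA with the Ovation RRBS Methyl-Seq kit. Per the labels' protocols, every mouse went through a model of Gulf War Illness. Corticosterone (CORT), the main glucocorticoid of rodents, was given in drinking water at 200 mg/L in 0.6% ethanol over 7 days. An injection of diisopropyl fluorophosphate (DFP), an irreversible inhibitor of acetylcholinesterase, followed on day 8 at 4 mg/kg, and courses of CORT were repeated until 5 weeks had passed. Saline or lipopolysaccharide (LPS, the endotoxin of Gram-negative bacteria, 0.5 mg/kg under the skin) was given on the last day, and tissues were taken at 6 h, 12 h or 24 h.

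The authors deposited 9 tables, 1 for each tissue and time, whose values are the percent methylation (0 to 100) of single cytosines on either strand in the saline and the LPS libraries of that comparison. Trim Galore, FastQC, Bismark, Bowtie2, SAMtools and methylKit are named with the mouse build GRCm38/mm10, per the submitters' processing notes, and their versions, settings, coverage minimum and any normalisation are not given in the sources used here. The tables held 1083654 to 1380165 cytosines each and no missing value. They gave no read counts, so the depth behind a value is unknown, no interval from counts can be given, and the coverage minimum could not be varied. The values of the saline libraries were identical in the 3 tables of a tissue wherever a cytosine stood in more than 1 of them. The 3 tables of a tissue held partly different cytosines (1060321 were common to all 3 in blood, 1108227 in hippocampus and 1268595 in cortex), so the saline mean of a gene can differ between times.

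Groups came from the labels: 4 saline, 4 LPS 6 h, 3 LPS 12 h and 3 LPS 24 h libraries of blood, 3, 4, 3 and 4 of hippocampus and 4 in each group of cortex. All saline samples were taken at 6 h, so at 12 h and 24 h the time since the injection differed as well as the injection. Nothing in the labels tells whether the replicates of a group are separate animals, so p-values measure the spread between these samples, which may be technical. Nor do the labels tell whether libraries of different tissues came from the same animals, so a pairing of tissues could not be taken into account. No library was a copy of another: any pair in a table had equal values at 48.4% of cytosines at most, levels of 0 and 100% included. The number of per-sample columns left unused was 0.

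Percent methylation was compared between LPS and saline with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided, Benjamini-Hochberg adjustment within a comparison). Single cytosines with a mean of 5 to 95% were called at an adjusted p under 0.05 and a difference of at least 10 points. Fixed tiles of 1000 bp (1 kb) with at least 3 cytosines were compared by their mean, with a difference of at least 5 points. A gene was the mean over its cytosines from 1000 bp before to 1000 bp after its span, called at the adjusted p with no minimum difference. The limit of 5 to 95% on the mean over both groups held for tiles and genes too. The table of mouse genes used (GRCm38.p6) gives spans but neither strand, exons nor transcript starts. The plan was to test promoters. As these could not be placed, whole genes took their place, and places are given only as inside or outside a gene span and within 1 kb of a gene end or not. Gene counts were therefore an addition to the plan.

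The mean over all cytosines of a table was compared between groups by an exact permutation test, two-sided with the smaller tail doubled. Its smallest p is 0.029 for 4 against 4 libraries, 0.057 for 3 against 4 and 0.1 for 3 against 3. The 19 gene lists were tested with limma's camera on gene means with a preset correlation of 0.01 and again with an estimated one, adjusted over all 171 tests (19 lists by 9 comparisons). Imprinted genes were listed among them as a control. As planned, fry was run beside camera with the same adjustment. LPS libraries of different times were compared in a joint limma fit on tiles found in all 3 tables of a tissue, and the difference of the LPS difference between tissues with a limma interaction contrast. Differences were correlated between tissues over tiles found in both, with a null from permuting the groups of the samples within each tissue, and between times beside values simulated for unchanged groups against the same saline libraries (20 simulations per pair of times). Further work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and arrow 21.0.0 in R.

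The groups, tests, call rules, gene lists and the rule for named genes were fixed before the data were examined. By that rule, the text names the 10 genes with the largest rise and the 10 with the largest fall among called tiles (1 tile per gene, the one with the smallest p), and where fewer than 5 passed it names 5 per direction by unadjusted p, said to be not past the test. It also names list members past the test over the list alone, and 13 fixed genes in each comparison. Some genes that the rule names are not reported here. Alternatives fixed at the same time were the logit scale, no filter on the mean, no or a larger minimum difference, centring of each library on its mean, the replicate number as a block, a joint fit of all times, at least 5 cytosines per tile, and leaving out each replicate. The strand classes described in the report, the exclusion of CpGs whose strands differ by 30 points or more, and cytosines within 1 kb of either gene end were added after seeing the data, as were lists of genes of all leukocytes and of markers of other tissues.

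The limma fits and camera for LPS against saline were tested on simulated data, drawn around the mean of each real item with its spread within groups. Items were drawn independently of one another, so this test cannot show how camera's preset correlation performs on correlated genes. For the fits, 100 items were changed by 10 points and 100 by 20 points, and all others were unchanged. Real blood held far more differences, which makes an adjusted p under 0.05 easier to reach, so the recovery given here does not describe real blood. At 20 points limma recovered 98 of the 100 genes in blood at 6 h, 92 in hippocampus and 98 in cortex. For tiles the recovery was 37 of 100 in blood at 6 h, 0 in hippocampus and 1 in cortex, and for cytosines it was 0 in all 9 comparisons. The joint fit of the times, the contrasts between tissues and fry were not tested in this way. A change of 20 points in so few tiles or cytosines of a brain region would therefore mostly go uncalled here.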

Results

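RRBS profiles of whole blood, hippocampus and frontal cortex were compared between LPS and saline in mice that had all received CORT and DFP, in a series whose title asks how far blood and brain respond together. Blood was represented by 4 saline libraries and by 4, 3 and 3 LPS libraries at 6, 12 and 24 h. Hippocampus was represented by 3 saline and 4, 3 and 4 LPS libraries, and cortex by 4 libraries in each of its groups. Each comparison covered 1083654 to 1380165 cytosines with a methylation level between 0 and 100%. The number of reads behind a level is unknown, so differences are set against the spread between libraries alone. Coordinates are those of GRCm38/mm10, and a tile is a fixed window of 1 kb.

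Whole blood DNA was more methylated after LPS at every time, as a mean over all cytosines. The mean level was 33.6% ± 0.179 (SD, n = 4) in saline and 35.5% ± 0.822 (n = 4) in LPS at 6 h. It was 31.5% ± 0.202 and 33.9% ± 0.738 (n = 3) at 12 h, and 32.8% ± 0.185 and 34.9% ± 1.08 (n = 3) at 24 h. All LPS blood libraries lay above the highest saline library (4 of 4, 3 of 3 and 3 of 3). Hippocampus went the other way at 6 h, from 25.8% ± 0.139 (n = 3) to 24.6% ± 0.324 (n = 4), with 4 of 4 LPS libraries below the lowest saline library. In hippocampus the means at 12 h were 30.9% ± 0.162 and 30.6% ± 1.72, and at 24 h 27.7% ± 0.139 and 27.1% ± 0.685. In cortex they were 31.2% ± 0.774 and 31.2% ± 0.830 at 6 h, 32.2% ± 0.769 and 32.0% ± 1.21 at 12 h, and 33.0% ± 0.810 and 33.2% ± 0.713 at 24 h. The exact two-sided permutation test gave p = 0.0286 in blood at 6 h, the smallest p possible for 4 against 4 libraries. It gave p = 0.0571 in blood at 12 h and 24 h and in hippocampus at 6 h, the smallest exact p possible for 3 against 4, a design that cannot reach 0.05. Adjusted over the 9 comparisons these 4 values became 0.129. The exact permutation p was 1 and 0.229 in hippocampus at 12 h (where 0.1 is the smallest possible) and 24 h, and 0.971, 0.743 and 0.514 in cortex. With the median over cytosines in place of the mean, the difference was 0.331 points in blood at 6 h (exact permutation p = 0.114), 0.117 at 12 h (0.8) and -0.113 at 24 h. It was 0.763 in hippocampus at 6 h, which like blood at 24 h was opposite to the difference of the means.

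**Figure D1:**
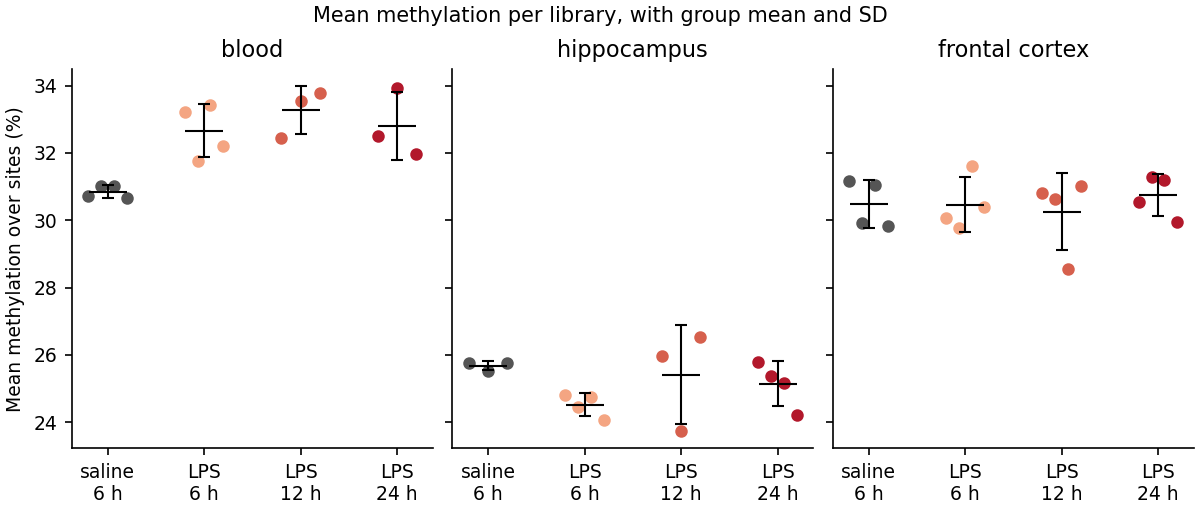
Mean methylation (percent, vertical axis) over the cytosines found in all 3 tables of a tissue, for each library of saline and LPS groups. Groups are by tissue and time, with points for libraries and bars for the group mean and SD. The levels differ from those in the text, which used all cytosines of each table. The blood LPS libraries lie above the saline ones at all 3 times, and the 4 hippocampal LPS libraries of 6 h below the saline ones.

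In blood at 6 h, LPS went with large shifts in both directions at single tiles of named genes. Uqcrc1, which encodes a core subunit of a mitochondrial respiratory complex, rose from 8.91% ± 2.35 (SD, n = 4) to 82.7% ± 10.01 (n = 4) at chromosome 9, 108949000 to 108949999, inside the gene and within 1 kb of its end (limma adjusted p = 2.97e-08). Spi1, a transcription factor of myeloid and B cells, fell from 72.7% ± 6.88 to 6.88% ± 4.82 at chromosome 2, 91097000 to 91097999, inside the gene (adjusted p = 2.62e-08). Of 74713 tiles, 22134 rose and 8822 fell, and of 12671 genes taken whole, 5375 rose and 1243 fell. Markers of neutrophils, the most abundant granulocytes, were mostly less methylated, by a median of -13.4 points.

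The other tiles with the largest rises lay inside their genes, more than 1 kb from the ends. Rad51b, a gene of homologous recombination, rose from 23.5% ± 5.45 to 91.8% ± 2.51 (chromosome 12, 79489000 to 79489999). Rab31, a small GTPase of vesicle transport, rose from 21.1% ± 4.61 to 87.4% ± 5.68 (chromosome 17, 65702000 to 65702999), and Rnf220, a ubiquitin ligase, from 20.5% ± 2.18 to 84.0% ± 4.67 over 52 cytosines (chromosome 4, 117304000 to 117304999). The kinase gene Taok3 rose from 21.6% to 88.1%, the guidance ligand Slit3 from 25.02% to 90.1%, Ccm2l from 25.03% to 89.4%, Rgmb from 31.8% to 95.8% and the lipoprotein receptor Scarb1 from 28.8% to 92.3%. Among the largest falls, Map3k20, a stress-activated kinase, went from 78.7% ± 6.99 to 7.47% ± 6.87 (chromosome 2, 72379000 to 72379999) and Armc9 from 79.5% ± 4.27 to 10.4% ± 7.29 (chromosome 1, 86191000 to 86191999). Arhgap45, a GTPase-activating protein of blood cells, fell from 69.2% ± 4.44 to 4.50% ± 3.79 within 1 kb of its end (chromosome 10, 80017000 to 80017999). Psd4 fell from 72.5% to 7.88%, the cAMP phosphodiesterase Pde4a from 71.3% to 7.18%, Ky from 69.0% to 5.51%, Klhl18 from 77.9% to 16.6%, Shisal1 from 67.9% to 7.05% and Pgm2 from 68.9% to 8.19%. The saline and LPS libraries did not overlap at any of these tiles, and their adjusted p ranged from 2.1e-08 to 6.81e-07.

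By place, 47.3% of tiles within 1 kb of a gene end, 45.1% of those farther inside genes and 36.2% of those outside protein-coding genes changed in blood at 6 h. By saline level, 48.7% of tiles under 20% changed, 83.3% between 20 and 50%, 68.0% between 50 and 80% and 18.1% at 80% or more. At the level of single cytosines, 102398 rose and 37958 fell of 497583, and 77457 of these changed by 25 points or more. When each library was centred on its own mean, 17467 tiles rose and 18959 fell, and 3295 genes rose and 4640 fell. Centring takes the same amount from every value of a library, so it lowers the excess of rises by construction. The shift was not the same at all tiles: those under 2% in saline rose by a median of 0.153 points. The median difference of all genes was 1.15 points as measured and -0.703 after centring.

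Neutrophil markers were the list set apart most clearly from other genes in blood at 6 h by camera with its preset correlation. Adjusted over the list alone, 10 of 13 measured markers fell, 1 rose and 2 did not pass, and over all genes the counts were 10 and 1. Cebpe, a transcription factor of granulocyte maturation, fell from 61.3% ± 3.92 to 25.8% ± 6.41 (n = 4 and 4). The granule proteases and enzymes Ctsg (73.0% ± 3.24 to 38.9% ± 1.40), Mpo (71.2% ± 1.48 to 40.4% ± 4.97), Mmp8 (67.8% to 38.8%) and Prtn3 (37.2% ± 0.278 to 8.55% ± 2.53) fell. So did the receptor Csf3r (61.9% to 46.1%), Camp (86.5% to 73.1%), Lcn2 (74.6% to 63.6%), Elane (82.5% to 74.1%) and Mmp9 (38.9% to 31.3%). Gfi1, a repressor in granulocyte differentiation, rose from 3.81% to 9.91%. The camera test of the list against all other genes gave an adjusted p = 1.06e-08, and adjusted p = 0.847 with an estimated correlation. Over the alternatives that adjusted p ranged from 3.38e-09 to 0.847, and with centring 11 markers fell and 1 rose.

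**Figure D2:**
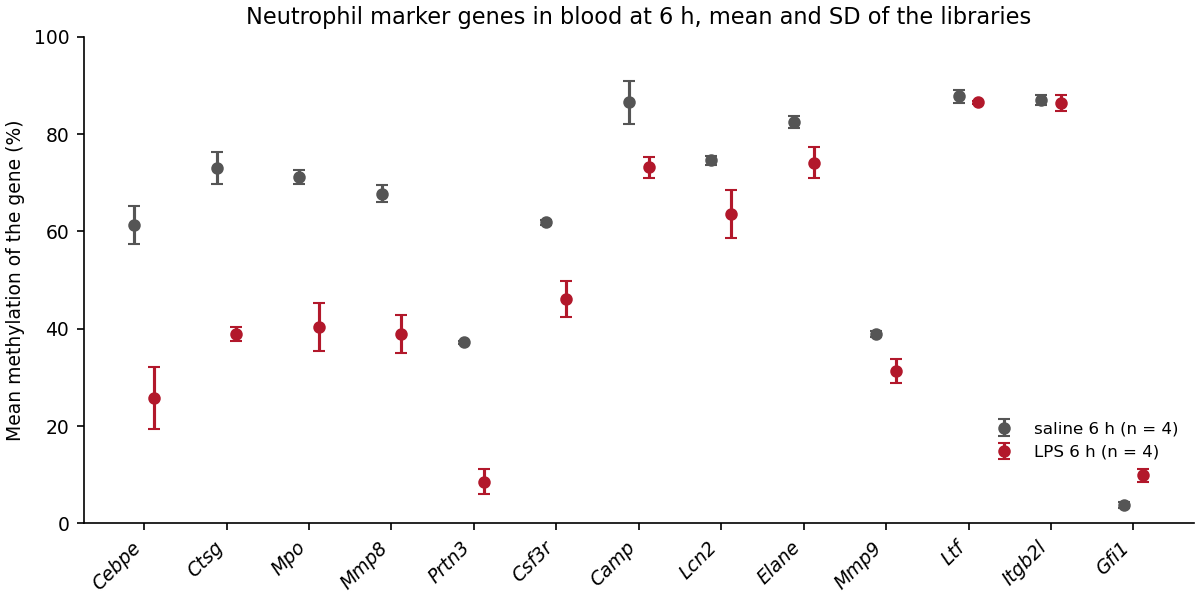
Methylation of neutrophil marker genes (percent, vertical axis) in the 4 saline and 4 LPS libraries of blood at 6 h, with points for group means and bars for the SD. Cebpe, Ctsg, Mpo and Prtn3 are lower in the LPS libraries, and Gfi1 is higher.

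Other markers of blood cells went both ways at 6 h, each count adjusted over the list alone. Of 15 microglia and macrophage markers, 3 rose (C1qc, Ctss and Apoe) and 5 fell (among them Spi1 from 67.2% ± 2.73 to 12.9% ± 4.68 over the whole gene, C1qb from 67.3% to 43.1%, Trem2 from 79.8% to 68.3% and Tmem119), with the same counts over all genes. Camera gave an adjusted p = 0.022 for this list and adjusted p = 0.99 with an estimated correlation, and 0.345 after centring and 0.177 near gene ends (0.0136 to 0.99 over the alternatives). Of 7 monocyte markers, 1 rose (Fcgr1, a receptor for IgG, 26.5% to 55.2%) and 3 fell (Fcgr4 from 67.1% to 35.6%). Of 21 T cell markers 9 rose and 6 fell, 9 and 5 over all genes: the T cell receptor component Cd3d fell from 48.1% ± 17.1 to 4.14% ± 2.64 and Lat from 80.8% to 62.4%, while Cd8a rose from 65.4% to 83.1%. Of 12 B cell markers 6 rose and 1 fell, with Cd79b, part of the B cell receptor, down from 29.0% ± 2.92 to 5.01% ± 3.16 and Cd37 up from 27.9% ± 6.77 to 63.5% ± 8.13. Of 5 NK cell markers 3 rose and 2 fell. Of 9 erythroid and platelet markers 2 rose (Nfe2 from 15.9% to 37.8%) and 3 fell, led by the platelet chemokine Pf4 (61.2% ± 5.67 to 6.06% ± 1.87), with the same counts over all genes for these 4 lists. After centring the rises and falls over the list alone were 3 and 9 for microglia, 1 and 4 for monocyte, 7 and 9 for T cell, 5 and 1 for B cell, 0 and 2 for NK cell, and 2 and 5 for erythroid and platelet markers. Camera gave adjusted p of 0.103 for monocyte, 0.459 for T cell, 0.981 for B cell, 0.7 for NK cell and 0.527 for erythroid and platelet markers.

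A measured fact stands beside all these blood groups. At 7 tiles in 7 leukocyte genes, picked after seeing the data for being under 10% in LPS blood at 12 h and over 50% in both saline brain regions, saline blood was partly methylated, at a median of 55.9% (range 40.1 to 61.9%). LPS blood at 6 h, which took no part in the choice, stood at 5.13%. Its tile differences correlated with those at 12 h at r = 0.985, so a low level was likely given the choice. Over all 117 tiles measured in the listed leukocyte genes, 32 rose and 37 fell. Vav1, a signalling protein of blood cells, was at 61.9% ± 4.04 in saline and 3.17% ± 3.95 in LPS at 6 h (chromosome 17, 57290000 to 57290999). The integrin gene Itgal was at 50.9% ± 2.64 and 7.03% ± 6.92 (chromosome 7, 127296000 to 127296999). Between 16.3 and 16.9% of cytosines lay at intermediate levels of 20 to 80% in saline blood libraries, and between 11.2 and 14.6% in LPS libraries at 6 h.

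Lists of signalling genes in blood mostly held more rises than falls at 6 h. That excess shrank or turned after centring, which lowers it by construction. Of 24 measured genes of cholinergic signalling, the pathway that DFP acts on, 14 rose and 10 did not pass, adjusted over the list alone and over all genes alike, and 9 rose and 4 fell after centring. Colq, the collagen tail of acetylcholinesterase, rose from 48.9% ± 3.52 to 88.7% ± 6.02, the muscarinic receptor Chrm1 from 43.8% ± 2.99 to 83.2% ± 6.63 and Chrna6 from 56.0% to 73.9%. Of 16 genes of the glucocorticoid response 9 rose and 7 did not pass (5 rose and 6 fell after centring), among them Klf9 from 10.6% to 16.2%, Zbtb16 from 37.2% to 43.2% and Sgk1 from 22.0% to 26.1%. Of 15 genes of the DNA methylation machinery 9 rose, 1 fell and 5 did not pass (7 and 6 after centring). Dnmt3l, a cofactor of the DNA methyltransferases, rose from 66.3% ± 3.16 to 85.9% ± 0.453 and Dnmt1 from 45.6% to 51.4%. Of 16 circadian genes 9 rose and 7 did not pass (4 and 5 fell after centring), with the repressor Nr1d1 up from 10.2% to 19.9%. Camera gave adjusted p of 0.357, 0.528, 0.527 and 0.527 for these 4 lists.

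Inflammatory genes in blood split at 6 h, adjusted over the list alone. Of 18 genes of Toll-like receptor and NF-kB signalling 6 rose and 3 fell (3 and 8 after centring). The cytokine gene Tnf rose from 64.9% ± 2.64 to 86.1% ± 4.46 and Nfkb1 from 17.5% to 23.0%, while the chemokine genes Ccl3 and Ccl4, whose values came from the same cytosines, fell from 74.4% ± 5.25 to 36.2% ± 4.96. Of 19 interferon response genes 8 rose and 6 fell, 7 and 6 over all genes (5 and 7 after centring), with Oas2 (49.8% to 23.6%) and Gbp3 (59.8% to 35.1%) lower and Xaf1 (11.1% to 18.3%) higher. Of 12 immediate early genes 6 rose and 5 fell, 4 and 5 over all genes (3 and 7 after centring), with Fosl2 up from 19.7% to 27.6% and Fosb down from 9.31% to 5.24%. Camera gave adjusted p of 0.565, 0.473 and 0.459. Over cytosines within 1 kb of either gene end, a region chosen after seeing the data, the first 2 lists passed camera with lower methylation (0.0455 and 0.0163), as did T cell markers (0.004) and erythroid and platelet markers (0.0356). None of these calls held there with an estimated correlation (adjusted p = 0.99, 0.682, 0.485 and 0.682). Over whole genes, for the first 2 lists, T cell markers and erythroid and platelet markers the median was above 0 (0.797, 1.69, 0.977 and 0.356 points) and the mean and the test pointed down (-2.82, -1.30, -1.47 and -2.62). For immediate early genes the median (-0.169) and the test pointed down and the mean (0.863) up, and for oligodendrocyte, endothelial and NK cell markers the test pointed down with a median and mean above 0.

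Genes of other cell types were also shifted in blood at 6 h. Of 26 synaptic and neuronal genes 17 rose and 2 fell adjusted over the list alone, 14 and 2 over all genes (7 and 4 after centring). Syn1, a synaptic vesicle protein, rose from 12.9% ± 2.41 to 41.2% ± 3.76 and the scaffold gene Dlg4 from 61.8% to 78.7%. Of 13 astrocyte markers 9 rose and 1 fell, 8 and 1 over all genes (6 and 1 after centring), with the water channel Aqp4 up from 29.9% to 65.7%. Of 12 oligodendrocyte markers 7 rose and 2 fell, 6 and 2 over all genes (4 and 4 after centring), with Cnp up from 27.3% to 37.4% and Mog down from 81.7% to 72.4%. Of 14 endothelial and pericyte markers 5 rose and 4 fell (5 and 7 after centring), with Pdgfrb up from 54.5% to 67.5% and Cdh5 down from 81.5% to 65.0%. Among 22 imprinted genes, whose alleles differ in methylation by parent, 3 rose (Usp29 from 57.7% to 68.1%) and 3 fell (Kcnq1ot1 from 48.0% to 34.4%, Zrsr1 from 43.3% to 33.5%), and 3 and 5 over all genes (2 and 9 over the list after centring). Camera gave adjusted p of 0.459, 0.497, 0.92 and 0.565 for the first 4 lists and 0.0319 for imprinted genes, the last with adjusted p = 0.99 with an estimated correlation and 0.455 after centring (0.0167 to 0.99 over the alternatives). The call on imprinted genes was lost without saline replicate 1 (0.0634), LPS replicate 1 (0.0524) or LPS replicate 4 (0.0636).

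The genes fixed for every comparison behaved as follows in blood at 6 h, by limma over all genes. Tnf, the corticotropin-releasing hormone receptor Crhr1 (22.0% to 26.3%, adjusted p = 0.000286), the demethylase Tet2 (23.3% to 27.3%, 0.000238) and the neurotrophin Bdnf (3.94% to 6.68%, 0.000253) rose. Values were 6.91% and 7.28% for Fkbp5, a cochaperone of the glucocorticoid receptor (0.19), 10.4% and 10.8% for acetylcholinesterase, Ache (0.533), 28.7% and 28.6% for Dnmt3a (0.929) and 86.5% and 82.5% for the inflammasome gene Nlrp3 (0.0557). The receptor gene Nr3c1 stood at 2.10% and 4.98%, below the range tested. After centring, Fkbp5 and Ache differed by -1.48 and -1.50 points (adjusted p = 0.00601 and 0.00441). Neither gene was lower as measured, so these differences come from the amount that centring subtracts. Il1b and Tlr4 had too few cytosines to be measured.

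In blood at 12 h (n = 4 saline and 3 LPS) the largest falls included Spi1 (to 3.70% ± 0.934 at the tile named above), P2rx7, an ATP-gated channel of immune cells (68.7% ± 4.39 to 2.82% ± 0.455, chromosome 5, 122678000 to 122678999) and Coro1a, an actin regulator of leukocytes (69.6% ± 4.01 to 5.43% ± 3.79, chromosome 7, 126703000 to 126703999, within 1 kb of its end). The others were Arhgap45 (to 1.73% ± 0.302), Pgm2 (to 0.758%), Armc9 (to 11.8%), Ky (to 2.57%), Pde4a (to 7.17%), Nomo1 (73.6% to 9.34%) and Angptl8 (74.8% to 9.48%, a tile shared with Dock6). The largest rises included Tle3, a corepressor (23.6% ± 2.29 to 93.9% ± 1.72, chromosome 9, 61405000 to 61405999), Rnf220 (to 90.6% ± 0.372), Rab31 (to 91.0% ± 0.859) and Uqcrc1 (10.6% ± 6.30 to 86.5% ± 9.86). Further rises were at H13 (17.2% to 88.6%), Taok3 (21.6% to 92.5%), Ccm2l (22.2% to 92.4%), Serping1, a complement inhibitor (19.1% to 89.2%), Tceal9 (19.7% to 88.4%) and Inppl1 (25.1% to 95.8%, near Phox2a). Of 61847 tiles 21393 rose and 6153 fell, and of 11984 genes 5757 rose and 952 fell, while centring gave 15248 and 14571 tiles and 3218 and 4382 genes.

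Of 12 neutrophil markers 9 fell at 12 h, adjusted over the list alone and over all genes, and none rose, with or without centring. Prtn3 fell to 6.36% and Cebpe from 60.9% to 20.5% (camera adjusted p = 1.05e-10, and adjusted p = 0.99 with an estimated correlation). Of 15 microglia and macrophage markers 4 rose and 5 fell, and camera placed the list lower than other genes (0.0266, adjusted p = 0.99 with an estimated correlation, and 0.501 after centring, with 3 rising and 7 falling). Of 22 imprinted genes 3 rose and 1 fell, with a median of -0.591 points against 1.65 for all genes, and camera placed the list lower (0.0353, adjusted p = 0.99 with an estimated correlation, and 0.585 after centring). The balance turned with centring, to 1 rising and 5 falling over the list alone and 2 and 7 over all genes. That call was also lost without saline replicate 1 (0.0689), LPS replicate 1 (0.115) or LPS replicate 3 (0.0519). Synaptic genes (19 of 24 rose, 1 fell), cholinergic genes (16 of 23 rose), interferon genes (11 of 18 rose, 3 fell) and Toll-like receptor and NF-kB genes (7 of 17 rose, 3 fell) had camera adjusted p of 0.273, 0.379, 0.651 and 0.7. After centring 8 and 3, 9 and 3, 4 and 6, and 4 and 8 of their members rose and fell. Near gene ends the interferon, Toll-like receptor and NF-kB, and T cell lists passed camera as lower at 12 h (0.0113, 0.0455 and 0.004) and at 24 h (0.0318, 0.041 and 0.004), and endothelial markers at 12 h (0.0455). With an estimated correlation none did (adjusted p = 0.682, 0.877, 0.485 and, for endothelial markers, 0.682 at 12 h, and 0.877, 0.877 and 0.682 at 24 h).

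At 24 h the largest blood falls again included Spi1 (to 2.04% ± 0.668), P2rx7 (to 1.55% ± 0.389), Arhgap45 (to 1.84%), Pgm2 (to 0.887%), Armc9 (to 9.41%), Psd4 (to 4.31%), Pde4a (to 5.64%), Angptl8 (to 4.53%), Ky (to 1.60%) and Acoxl (71.4% to 5.65%, chromosome 2, 128063000 to 128063999). The largest rises were at Uqcrc1 (to 87.2% ± 2.55), Tle3 (to 95.3%), Rab31 (to 91.5%), Rnf220 (20.6% to 90.8%), Ccm2l (to 92.5%), Tceal9 (to 89.9%), Rad51b (to 93.2%) and Slit3 (to 92.7%), followed by Rasal3, a Ras GTPase-activating protein (22.5% to 91.3%, chromosome 17, 32396000 to 32396999) and Cavin3 (22.7% to 92.3%), with n = 4 saline and 3 LPS. Of 71782 tiles 22344 rose and 8134 fell, and of 12505 genes 5107 rose and 1108 fell, and after centring 17224 and 17173 tiles and 3203 and 4009 genes.

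Of 13 neutrophil markers 10 fell and 1 rose at 24 h, adjusted over the list alone and over all genes, and 11 and 1 after centring. Prtn3 fell to 5.21% and Cebpe to 18.8% (camera adjusted p = 8.51e-09, and adjusted p = 0.99 with an estimated correlation). Of 22 imprinted genes 1 rose and 2 fell over the list alone, and 2 and 4 over all genes (0.0102, and adjusted p = 0.99 with an estimated correlation, 0.302 after centring, 0.000113 to 0.99 over the alternatives). After centring 1 rose and 12 fell over the list alone, and 1 and 11 over all genes. Of 15 microglia and macrophage markers 3 rose and 5 fell, and camera placed the list lower (0.0397, and adjusted p = 0.99 with an estimated correlation). That call was lost after centring (0.394, with 2 rising and 8 falling), on the logit scale (0.0541), near gene ends (0.0717), with the replicate block (0.0597) and without saline replicate 1 (0.0586) or saline replicate 4 (0.0821). Fkbp5 rose from 6.91% to 7.65% (limma adjusted p = 0.0467 over all genes). That call was lost in 5 of the 7 fits that left out a library (saline replicate 1, 3 or 4 or LPS replicate 1 or 2), and after centring the difference was -1.18 points (adjusted p = 0.0388). Tnf was at 88.8% at 12 h and 89.2% at 24 h.

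LPS blood libraries of different times differed at few tiles, 2 at most over the alternatives. In a joint limma fit 1 tile differed between 12 h and 6 h, at chromosome 17, 17909000 to 17909999, with no protein-coding gene within 1 kb (named after its values were seen). It stood at 11.3% ± 2.69 in saline, 25.3% ± 2.23 at 6 h, 9.24% ± 1.60 at 12 h and 16.4% ± 4.34 at 24 h (adjusted p = 0.0394). That call was lost in 6 of the 7 fits that left out a library, all but the one without LPS 6 h replicate 1. No tile differed between 24 h and 6 h or between 24 h and 12 h (limma, 2932 and 2192 tiles at an unadjusted p under 0.05, and 3618 for 12 h against 6 h). Tile differences of separate times correlated at r = 0.985 (6 h and 12 h), 0.984 (6 h and 24 h) and 0.984 (12 h and 24 h) across tiles, which are not independent replicates. All times shared the same saline libraries, and unchanged groups simulated against them gave r = 0.463, 0.464 and 0.428 and covariances of 3.02, 3.02 and 3.01, beside observed covariances of 188.4, 189.2 and 200.5. With the saline libraries split between the times, r was 0.960, 0.960 and 0.961. Tiles that rose at both 6 h and 12 h numbered 17583, against 6583 for independent lists, and those that fell 5344, against 707. The values for independent lists leave out the shared saline libraries, so part of the excess may come from these.

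In hippocampus at 6 h, methylation of many genes was lower after LPS by a few points. Impact, an imprinted gene expressed in neurons, fell from 37.2% ± 0.786 (n = 3) to 24.6% ± 1.21 (n = 4) over the whole gene (limma adjusted p = 0.00499 over all genes). Of 11159 genes 724 fell and 2 rose, and the median difference of all genes was -0.990 points. The genes that rose, named after their values were seen, were Nlrp1b, an inflammasome sensor (82.6% ± 1.30 to 91.2% ± 2.77, adjusted p = 0.0425), and Cldn34b1 (78.2% ± 1.61 to 83.9% ± 0.888, adjusted p = 0.0433). No tile and no single cytosine was called by limma (11452 tiles and 42723 cytosines had an unadjusted p under 0.05), while 72 tiles were called among those with at least 5 cytosines.

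Imprinted genes, synaptic genes and astrocyte markers were lower than other genes in hippocampus at 6 h by camera with its preset correlation, and none was so with an estimated correlation (adjusted p = 0.99 for each). Imprinted genes were the control list, and with the preset correlation they also passed in blood at 6, 12 and 24 h and in cortex at 24 h. The preset test thus called the control as well as other lists. Of 22 imprinted genes 13 fell adjusted over the list alone and 6 over all genes, and none rose, among them H19 (62.7% to 49.97%), Meg3 (31.0% to 21.6%), Sgce (42.2% to 28.5%) and Snrpn (60.0% to 51.0%). Of 23 synaptic and neuronal genes 16 fell over the list alone and 6 over all genes, among them the glutamate receptor subunits Gria1 (45.6% ± 1.62 to 39.4% ± 2.19) and Grin2b (39.4% to 35.5%), Dlg4 (32.1% to 28.9%), Stx1a (33.8% to 30.8%) and Syt1 (57.3% to 53.5%). Of 11 astrocyte markers 7 fell over the list alone and 3 over all genes, with Aqp4 down from 30.4% ± 2.96 to 20.6% ± 1.82 and the glutamate transporter Slc1a2 from 18.5% to 15.7%. Camera with the preset correlation gave adjusted p of 0.0127, 0.0266 and 0.0379. After centring, 12 imprinted genes fell and 1 rose and 2 astrocyte markers fell over the list alone, no synaptic gene passed, and the camera values were 1.69e-05, 0.188 and 0.0375 (over the alternatives 1.69e-05 to 0.99, 0.0171 to 0.99 and 0.00494 to 0.99). The synaptic call was lost without saline replicate 1 (0.0794) or LPS replicate 4 (0.0515), and the astrocyte call without saline replicate 1 (0.0774), saline replicate 2 (0.102), LPS replicate 3 (0.0918) or LPS replicate 4 (0.124). Both were lost with the replicate block (0.0673 and 0.0646) and near gene ends, where the synaptic list turned upward (0.663 and 0.905), and the astrocyte call with strand discordance as a covariate (0.0901).

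Members of other lists fell in hippocampus at 6 h, adjusted over the list alone, without their list passing camera. These were 8 of 19 T cell markers, such as Zap70 (58.9% to 53.9%), and 4 oligodendrocyte markers, among them Sox10 (9.37% to 7.47%). The list of glucocorticoid response genes had 3 falls (Hif3a, Nfkbia and Zbtb16) and endothelial markers 3. DNA methylation genes had 2 falls, microglia markers 2 (among them P2ry12), and Nfkb1, Trim25, Nr4a2 and Itga2b fell in 1 list each. After centring no member of the T cell, oligodendrocyte, glucocorticoid, endothelial, DNA methylation or microglia lists passed, and 3 genes of Toll-like receptor and NF-kB signalling rose over the list alone. So did 1 cholinergic gene, while 1 interferon gene fell, and 1 erythroid or platelet marker rose and 1 fell. None of these passed over all genes. As measured, no member passed among cholinergic, circadian, neutrophil, monocyte, B cell or NK cell genes. The count of 726 genes rested on single libraries: it was 0 without saline replicate 1, 5 without saline replicate 2, 0 without saline replicate 3, 3, 1, 246 and 179 without LPS replicates 1 to 4, and 1 after centring each library.

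The tiles with the smallest p in hippocampus at 6 h, none past the test, were lower at Impact (36.5% ± 1.02 and 17.8% ± 2.13 over 32 cytosines, chromosome 18, 12973000 to 12973999). They were also lower at Etv6, a transcriptional repressor (25.9% ± 3.21 and 5.60% ± 2.77, chromosome 6, 134147000 to 134147999), Sh3bp5 (36.3% and 16.8%), Rwdd3 (34.1% and 14.2%) and the striatal phosphodiesterase gene Pde10a (87.2% and 62.3%), each with adjusted p = 0.074. They were higher at the potassium channel gene Kcnq3 (40.7% and 63.8%, 0.0925), 3830403N18Rik (86.7% and 95.4%), Thsd4 (91.1% and 97.9%), the inflammasome sensor Nlrp1b (78.9% and 90.0%, 0.102) and Dnah17 (83.3% and 93.4%).

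At 12 h no hippocampal cytosine, tile or gene was called by limma (25770 cytosines, 2583 tiles and 275 genes at an unadjusted p under 0.05, n = 3 and 3), and no list or list member passed. Without LPS replicate 2, however, 8445 cytosines, 67 tiles and 397 genes were called, and 375 tiles and 2234 genes were called with the class of strand discordance of the library as a covariate, a fit in which the LPS difference rests on LPS replicate 2 alone. These sets of calls ran in opposite directions. Without replicate 2, 394 of the 397 genes and all 67 tiles were higher, and with the covariate 2228 of the 2234 genes and all 375 tiles were lower. The difference in mean methylation was 0.585 points without replicate 2 and -2.35 with replicate 2 as the LPS library. Tiles with the smallest p, all with adjusted p = 1, were at Vwa8 (21.9% and 48.5%), Wfdc8, Wwc1, Maml3 and Rfx3 on the higher side. On the lower side they were at transferrin, Trf (86.6% and 56.9%, chromosome 9, 103213000 to 103213999), the neuronal splicing factor Rbfox3 (41.5% and 16.2%), Sag, Tbx19 and G6pc. At 24 h again no cytosine, tile or gene was called (28445, 5239 and 1137 at an unadjusted p under 0.05, n = 3 and 4). Adjusted over the list alone 6 members fell, among them Dlg4, Esam, Cd4, H19 (60.5% to 50.8%) and Impact (37.2% to 25.3%), and none over all genes (Impact 0.0933), with no list past camera. The 24 h tiles of smallest p, not past the test, were at Gng7 (56.2% and 30.0%), Bbs9 (50.5% and 16.8%), Rbm26, Impact (36.5% and 18.5%) and Cd300lb on the lower side (0.344 to 0.356). On the higher side they were at Syde2, Nlrp1b (78.9% and 90.6%), Grip1, Cgnl1 and Dipk1a.

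In frontal cortex no cytosine, tile or gene was called by limma at any time (n = 4 and 4). At an unadjusted p under 0.05 there were 15216 cytosines, 2225 tiles and 181 genes at 6 h, 16537, 2353 and 187 at 12 h, and 18258, 2612 and 288 at 24 h. The tiles with the smallest p, all with adjusted p = 1, included Apba1, a neuronal adaptor of the presynapse (83.9% and 94.4% at 6 h, 92.3% at 12 h, chromosome 19, 23947000 to 23947999), Gm4869, Nxpe2, Hpse2 and Dlg2 on the higher side at 6 h. On the lower side they included Itga9 (54.8% and 35.5%), Acsl6, Lpar6, Celf4 and Ppp2r5c. At 12 h they were Cenpt, Lrrc51, Chmp2b and Itga6 (higher) and Mideas (45.2% and 16.1%), Kctd8, Rbfox1, Gse1 and Napa (lower). At 24 h they were the astrocyte glutamate transporter Slc1a3 (73.2% and 86.8%), Btbd17 (18.1% and 42.7%), Eif4g3, Tbc1d9 and Hapln3 (higher) and Adgb, Lrig3, Gnb5, Eppk1 and Got2 (lower). None of the fixed genes passed in either brain region.

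Lists passed camera in cortex with hardly a member past its own test. T cell markers were higher at 6 h (21 measured, none past the test, median 0.443 points, adjusted p = 0.0256), NK cell markers at 12 h (6 measured, median 1.40, adjusted p = 0.0397) and imprinted genes at 24 h (22 measured, median 1.29, adjusted p = 0.0212), each with adjusted p = 0.99 with an estimated correlation. Klra8, a receptor of NK cells, rose from 66.8% ± 1.75 to 71.4% ± 1.48 adjusted over the list alone (0.0372) and did not pass over all genes. The T cell call was lost without saline replicate 2 (0.0869) or LPS replicate 4 (0.198) and near gene ends (0.997). The NK cell call was lost without saline replicate 2 (0.177), 3 (0.162) or 4 (0.0506) or LPS replicate 1 (0.263) or 3 (0.353) and after centring (0.244), and the imprinted call without saline replicate 3 (0.143) or 4 (0.167) or LPS replicate 2 (0.0929) or 3 (0.107).

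With all libraries in the fit, no tile was called between LPS times in either brain region (joint limma fit, 3106, 2580 and 1640 tiles in hippocampus and 2036, 2106 and 2465 in cortex at an unadjusted p under 0.05). Without single libraries, hippocampus gave 0 to 70 tiles for 12 h against 6 h and 0 to 4 for 24 h against 12 h. In hippocampus the differences correlated at r = 0.641 (6 h and 12 h), 0.741 (6 h and 24 h) and 0.659 (12 h and 24 h), beside 0.533, 0.571 and 0.534 simulated for unchanged groups. The covariances were 8.20, 10.4 and 7.06 beside 5.56, 5.58 and 5.58, and part of this excess may come from the 3 shared saline libraries, which are too few to split. In cortex r was 0.547, 0.488 and 0.447 beside simulated values of 0.500, 0.500 and 0.501, with covariances of 3.70, 3.11 and 2.88 beside 4.74, 4.74 and 4.76. With the cortex saline libraries split, r was 0.00165, -0.0556 and -0.0767.

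The differences of blood and brain were set side by side over tiles measured in both. At 6 h r was -0.135 for blood and hippocampus (permutation p = 0.0114, adjusted over 9 relations 0.103), -0.0269 for blood and cortex (permutation p = 0.57) and 0.0174 for hippocampus and cortex (permutation p = 0.839). At 12 h r was -0.0703, -0.0803 and 0.0622 (permutation p = 0.534, 0.394 and 0.854), and at 24 h -0.0989, 0.0563 and -0.103 (permutation p = 0.114, 0.242 and 0.176). Tiles are not independent replicates, so the groups of the samples were permuted. They were permuted in each tissue separately, so these p-values leave out any pairing of tissues from the same mouse. The LPS difference itself differed between blood and hippocampus at 24071, 19172 and 20379 tiles at the 3 times in order (limma interaction), and between blood and cortex at 20786, 19834 and 21601. Between hippocampus and cortex it differed at 0, 0 and 1 tiles (5922, 2022 and 4253 at an unadjusted p under 0.05). This tile, named after its values were seen, lay inside Rbm26, an RNA-binding protein gene (chromosome 14, 105168000 to 105168999). It stood at 28.5% ± 2.84 and 8.72% ± 3.60 in saline and LPS hippocampus and 26.8% ± 2.60 and 34.7% ± 3.73 in cortex (adjusted p = 0.0262). The Rbm26 call was lost in 11 of the 15 fits that left out a library, and held without hippocampus LPS replicate 1, cortex saline replicate 3 or cortex LPS replicate 3 or 4.

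Saline samples differed between tissues at many tiles. This sets the tissues apart but does not show that each library held its labelled tissue alone. Hippocampus was above blood at 11547 tiles and below it at 12208 of 46042 (limma), cortex above blood at 14104 and below at 12962 of 54686, and cortex above hippocampus at 5793 and below at 2657 of 50179. Across 82953 tiles the levels of saline blood correlated at r = 0.941 with LPS blood at 6 h, 0.929 with saline hippocampus and 0.937 with saline cortex, LPS blood at 0.886 and 0.901 with the same brain groups, and hippocampus with cortex at 0.985.

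Libraries also differed in a way the groups do not name. In 17 libraries between 0.951 and 1.82% of CpGs had strands that differed by 50 points or more, in 8 cortex libraries between 0.0487 and 0.116%, and in all others between 0.0129 and 0.0297%. The first kind made up 2 of 4 saline, 2 of 4, 2 of 3 and 2 of 3 LPS libraries of blood, and 1 of 4 in every group of cortex. In hippocampus they were 0 of 3 saline and 1 of 4, 2 of 3 and 2 of 4 LPS libraries, so the kind of library went partly with LPS there. Within blood at 6 h, 26900 tiles were called among the libraries of the first kind and 20732 among the others, against 30956 in all. Among the others, 4130, 4079 and 4100 genes and 58083, 0 and 0 cytosines were called in blood at the 3 times in order, with 1 LPS library left at 12 h and at 24 h that is assumed to vary like the others. In hippocampus at 6 h, 179 genes were called without libraries of the first kind and 176 with the kind as a covariate, against 726.

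**Figure D3:**
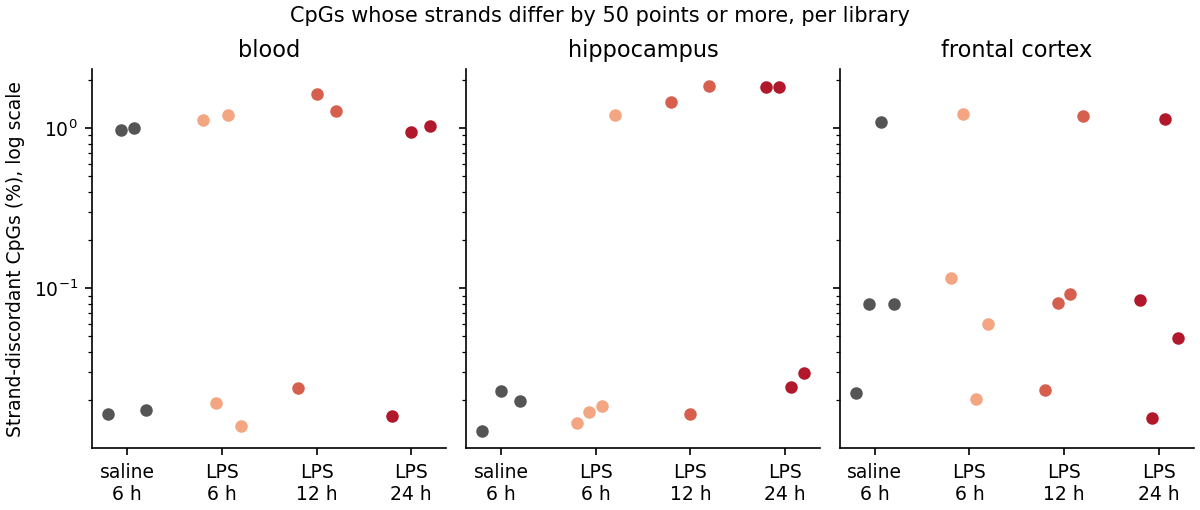
Share of CpGs (percent, logarithmic vertical axis) whose 2 strands differ by 50 points or more, for each of the 44 libraries by tissue and group. The 17 libraries between 0.951 and 1.82% stand apart from the other libraries in all 3 tissues.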

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

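The splits of the samples, the tests of cells of another tissue in saline blood, of LPS exposure and a strain variant behind strand-discordant libraries, and both tests in hippocampus were chosen only after the result was seen, and those of conversion, blood cell shares and tissue were not.

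Saline and LPS blood differed at 30956 tiles at 6 h, with similar counts at the later times. Incomplete conversion in the LPS libraries is argued against, since 17899 tiles under 2% in saline rose by a median of 0.153 points while Spi1 fell from 72.7% to 6.88%. Cells of another tissue in the saline blood libraries are a candidate explanation: 7 tiles of leukocyte genes, picked for being under 10% in LPS blood at 12 h and over 50% in both brain regions, stood at a median of 55.9% in saline blood, at 50.8 to 62.1% in its single libraries, and tiles low in only part of the leukocytes would look the same. Over all shared tiles saline blood correlated with saline hippocampus and cortex at r = 0.929 and 0.937, and LPS blood at 6 h at 0.886 and 0.901. These correlations were not made as a test of that explanation. A change in the share of blood cell types cannot be told apart from a change within cells, because LPS 6 h replicate 2, which lay between the groups, moved with slopes of 0.780 at tiles that rose and 0.845 at tiles that fell, a gap of 0.0646 where other libraries had gaps up to 0.141. LPS itself stays among the open explanations, as no blood from untreated mice was used here.

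For blood, 1 of 35 splits, the real one, gave as many cytosines, tiles or genes at each time, so chance is excluded for these counts. The bar used for this was a share under 0.05 with no adjustment over comparisons, and 1 of 35 is the lowest share possible. The real values at 6 h were 140356 cytosines, 30956 tiles and 6618 genes, against 6166, 119 and 317 in the highest other split. They were 124508, 27546 and 6709 against 4861, 92 and 223 at 12 h, and 138553, 30478 and 6215 against 5254, 0 and 117 at 24 h. For the 3 lists past camera in blood chance is not excluded, as 6, 7 and 6 of 35 splits gave as many at 6 h, 12 h and at 24 h, with 4 in the highest other split each time.

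In 17 of 44 libraries the strands of 0.951 to 1.82% of CpGs differed by 50 points or more. LPS exposure as the whole cause is argued against, since 3 of 11 saline libraries were of this kind beside 14 of 33 LPS libraries (Fisher's exact test, two-sided p = 0.486). A variant of the strain is argued against, since the lowest share in a library of this inbred strain was 0.00708 of the highest. Tissue is argued against, since 79.4% of the 1909 discordant CpGs of blood that were measured in cortex were discordant there too, against 0.824% by chance, and 89.3% of 2014 in hippocampus. A difference between library or sequencing batches stays open and was not tested, as the labels give no batch.

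The same feature made 5 libraries stand apart within their groups of 4. These were hippocampus LPS 6 h replicate 4 at 1.202% (others 0.0144 to 0.0183%), cortex saline replicate 3 at 1.092% (0.0223 to 0.0792%), cortex LPS 6 h replicate 2 at 1.218% (0.0205 to 0.116%), cortex LPS 12 h replicate 4 at 1.196% (0.0232 to 0.0915%) and cortex LPS 24 h replicate 3 at 1.143% (0.0155 to 0.0843%). Of 176 groups of 4 values tested in this way 11 held such a value, and chance gives about 1 in 20.

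Hippocampal genes were lower after LPS at 6 h, 724 of the 726 called. Strand discordance of single libraries as the whole cause is argued against, since 179 genes were called without the discordant library. A shift of whole libraries cannot be told apart from changes of single genes: after centring 1 gene was called, the median difference of all genes went from -0.990 to 0.114 points, and that of imprinted genes from -5.81 to -4.71. Why the calls ended was not tested. LPS stays among the open explanations.

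For hippocampus at 6 h, 1 of 35 splits gave as many genes (726 against 0 in the highest other split). This share is under 0.05, but it is the lowest possible and is not adjusted over comparisons. The gene count was 0 to 246 without single libraries and 1 after centring, so chance is not firmly excluded for it. For lists it was also 1 of 35, the lowest share possible, but with a margin of only 3 against 2. The list count was 0 with an estimated correlation and 1 without saline replicate 1 or LPS replicate 4. Chance is therefore not firmly excluded for the lists. The counts of 0 cytosines and 0 tiles there were matched by 35 of 35 splits, with 0 the highest, by limma with 42723 and 11452 at an unadjusted p under 0.05. At 12 h the 10 splits of 3 against 3 libraries are too few for a share under 0.05, with real values of 0 cytosines, tiles, genes and lists and highest other values of 0, 0, 0 and 1 (limma, 275 genes at an unadjusted p under 0.05). At 24 h all 35 of 35 splits gave at least the real values of 0, with highest other values of 226 cytosines, 11 tiles, 6 genes and 2 lists (limma, 1137 genes at an unadjusted p under 0.05).

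In cortex the real values of 0 were matched by 35 of 35 splits (limma, 181, 187 and 288 genes at an unadjusted p under 0.05). The highest other splits gave 14400 cytosines, 24 tiles and 143 genes at 6 h, 18478, 147 and 188 at 12 h, and 23558, 1824 and 2328 at 24 h. Counts this high in splits other than the real one point to a structure of the samples. Each of these put both strand-discordant libraries on one side, but other splits do so too, so this does not show which feature they follow. Among the libraries left without the discordant ones, limma called 0 cytosines, tiles and genes in LPS against saline. The 8 cortex libraries with an intermediate share of discordant CpGs (0.0487 to 0.116%) were not set apart in that check. For the 1 list past camera at each time chance is not excluded, as 7, 13 and 7 of 35 splits gave as many, with 2, 3 and 1 in the highest other split.

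The LPS difference differed between tissues by the interaction test, in counts set against 100 splits. For blood and hippocampus it differed at 24071, 19172 and 20379 tiles at the 3 times, a count reached by 1 of 100 splits each time, with 19517, 18595 and 17124 in the highest other split. For blood and cortex it differed at 20786, 19834 and 21601 tiles, reached by 1, 3 and 3 of 100 splits, with 5, 21651 and 22455 in the highest other split. These shares are under 0.05 for all 6 counts, but the splits regrouped blood and brain together. Only 3, 3 and 2 draws for hippocampus and 0, 4 and 2 for cortex kept the blood grouping. With blood regrouped the highest were 50, 1 and 5 for hippocampus and 5, 9972 and 7 for cortex. At 12 h and 24 h, cortex regrouped with blood kept gave more tiles than the real grouping. The counts thus mostly follow the blood difference, and chance is excluded for that difference only. Between hippocampus and cortex 1 tile, in Rbm26, differed at 24 h, a count reached by 8 of 100 splits with 453 the highest, so chance is not excluded. At 6 h and 12 h 0 differed (limma, 5922 and 2022 at an unadjusted p under 0.05), a count that any split reaches, with 83 and 1 the highest.

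Between times, 1 tile differed in blood between 12 h and 6 h, a count reached by 5 of 35 splits with 1 the highest other, so chance is not excluded. The real values of 0 (limma, 2932 and 2192 blood tiles at an unadjusted p under 0.05) were reached by 35 of 35 splits for 24 h against 6 h, with 4 the highest, while for 24 h against 12 h the 10 splits are too few for a share under 0.05, with 83 the highest (10 of 10 reached 0). In hippocampus (limma, 3106, 2580 and 1640 at an unadjusted p under 0.05) and cortex (2036, 2106 and 2465) the counts of 0 were reached by 35 of 35 splits, with 93, 1 and 604, and 1, 0 and 1 the highest. Between saline tissues the 23755, 27066 and 8450 tiles that differed were reached by 1 of 35 splits each, with 0 in the highest other split (limma), so chance is excluded.

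The mean over cytosines found in all tables was 28.55% in cortex LPS 12 h replicate 3 and 30.64 to 31.0% in the other 3 libraries of its group. The Shisal1 and Pgm2 tiles of blood LPS 6 h replicate 2 stood at 14.15% and 19.8%, against 4.01 to 5.59% and 3.83 to 4.66% in the others. The Thsd4 tile stood at 95.35% in hippocampus LPS 6 h replicate 4 (others 98.41 to 99.02%), the Cgnl1 tile at 90.68% in hippocampus LPS 24 h replicate 2 (97.37 to 97.92%) and the Gm4869 tile at 66.86% in cortex saline replicate 3 (69.64 to 70.02%).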

How the results depend on the processing

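Fits by strand discordance, CpGs with discordant strands left out, cytosines within 1 kb of a gene end, and all settings of the gene counts, time contrasts and tissue interactions were chosen only after the result was seen. The coverage minimum could not be varied and no depth is given, so no result can be weighed by reads. Of the named tiles past the test, all 1121 alternative values kept direction and call, and those not past it gained the call in 4 of their values. The tiles past the test were named for their small p and large differences, so this says little about the other called tiles. Lists past camera kept both in 143 values, lost the call in 57 and turned in 1, and those not past it gained it in 23 of their values. Fixed genes past the test kept both in 175 values, lost the call in 10 and turned in 1, and those not past it gained it in 8 in the same direction. The cause was not tested for any change given here, except where fewer libraries, cytosines or a larger minimum difference make fewer calls by construction.

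In blood at the 3 times in order, a minimum difference of 25 points left 77457, 71160 and 81478 cytosines, and at least 5 cytosines per tile left 17311, 15281 and 17129 tiles. Among libraries without strand discordance 4130, 4079 and 4100 genes and 58083, 0 and 0 cytosines were called, with 1 LPS library at 12 h and at 24 h, and among the discordant ones 3629 genes at 24 h. Lists past camera numbered 1, 1 and 1 after centring, 0, 0 and 0 with an estimated correlation and 6, 7 and 5 near gene ends.

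In hippocampus at 6 h the gene count was 1 with no filter, 1 after centring, 176 with strand discordance as a covariate, 179 without the discordant library and 0 to 246 without single libraries. The tile count was 72 with at least 5 cytosines per tile and 0 to 2 without single libraries. Lists numbered 0 with an estimated correlation, 1 near gene ends and 1 to 4 without single libraries. At 12 h the discordance covariate gave 2234 genes (2228 lower), 375 tiles (all lower) and 2 lists, resting on LPS replicate 2, the only LPS library without discordance. That library against saline gave 1423 genes, 1422 of them lower, and the logit scale 1 tile. Single libraries left out gave 0 to 397 genes, 0 to 8445 cytosines and 0 to 67 tiles. The highest came each time without LPS replicate 2, and 394 of those genes and all of those tiles were higher. At 24 h centring gave 1 gene and 1 list, the covariate 3 lists, and single libraries left out 0 to 1 genes, the highest without LPS replicate 1. The library left alone in an arm is assumed to vary like the others.

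In cortex, list counts were 0, 0 and 0 with an estimated correlation, 0 near gene ends at 6 h, 2 with the covariate at 12 h, and 0 to 2, 0 to 2 and 0 to 1 without single libraries. The count of 1 at 12 h stayed 1 after centring, but the NK cell list (0.244) gave way to the synaptic list (0.0375).

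With the median in place of the mean over cytosines, the difference was 0.331, 0.117, -0.113, 0.763, 0.0742 and 0.0329 points in blood at the 3 times, hippocampus at 6 h and 24 h and cortex at 6 h. The difference of the means in blood at 6 h was 2.46 among discordant and 1.38 among other libraries and 1.65 to 2.22 without single libraries, too few for an exact p under 0.05. In cortex at 6 h it was 0.405 among other libraries. Without single libraries it was -0.416 to 0.224 in cortex at 6 h and -0.506 to 0.365 at 12 h, and -1.04 to 0.585 in hippocampus at 12 h. It was 0.016 to 0.561 in cortex and -0.783 to -0.241 in hippocampus at 24 h.

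The replicate numbers do not pair the samples: same-numbered libraries correlated at -0.188 to 0.23, in no comparison over 0.1 in every pair. With the replicate number as a block, 0 genes (limma, 3484 at an unadjusted p under 0.05 without the block) and 1 list were called in hippocampus at 6 h, and 30788, 26219 and 28466 tiles in blood. The mean difference in blood at 6 h stayed at 1.92 points, with an exact p of 0.125, the smallest that 4 pairs allow. Calls were also lost for Fkbp5 (adjusted p = 0.0764) and microglia and macrophage markers (0.0597) in blood at 24 h and for the synaptic and astrocyte lists in hippocampus at 6 h (0.0673 and 0.0646). The block changed no other call and no other count by over 1.5 times. In no comparison did every library correlate best with its own number.

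For tiles that differed between times, blood 12 h against 6 h gave 0 on the logit scale, 0 with no filter, 0 among discordant and 0 among other libraries, and 0 to 2 without single libraries. Blood 24 h against 6 h gave 2 on the logit scale and 0 to 2 without single libraries. Hippocampus 12 h against 6 h gave 1 among other libraries and 0 to 70 without single libraries, 24 h against 12 h 0 to 4, and cortex 24 h against 6 h 1 with no filter. Between hippocampus and cortex the interaction gave 0 tiles at 24 h on the logit scale, and 0 to 8, 0 to 1 and 0 to 1 at the 3 times without single libraries.

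Correlations between tissues over cytosines in place of tiles were -0.104 for blood and hippocampus at 6 h, 0.00507 at 12 h and -0.00349 for hippocampus and cortex at 6 h. Among libraries without discordance they were 0.0380 for blood and cortex at 6 h, -0.107 for blood and hippocampus at 24 h and -0.206 for hippocampus and cortex at 6 h. The value at 24 h rests on LPS replicate 1 alone in blood. Without single libraries r was -0.0857 to 0.0354 and -0.1247 to 0.0177 for blood and cortex at 6 h and 12 h, -0.108 to 0.0358 for blood and hippocampus at 12 h, and -0.214 to 0.213, -0.0882 to 0.123 and -0.194 to -0.0130 for hippocampus and cortex. Between times in cortex, split controls gave 0.00165, -0.0556 and -0.0767, as those comparisons then share no library.

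Fixed genes turned direction as follows, in points. After centring the differences in blood were -1.48, -1.87 and -1.18 for Fkbp5 at the 3 times, -1.50 and -1.61 for Ache at 6 h and 24 h, and -1.01 for Nlrp3 at 12 h. Those of Fkbp5 and Ache passed as lower (adjusted p = 0.00601, 0.00326 and 0.0388, and 0.00441 and 0.0275). As measured neither gene was lower, so these calls come from the amount that centring subtracts. The centred differences were 0.218, 0.0773 and 0.0719 for Crhr1 and 0.310 and 0.0156 for Dnmt3a in hippocampus, and 0.11988 for Crhr1 at 12 h and -0.178, -0.0265 and -0.129 for Dnmt3a, Nlrp3 and Tet2 at 24 h in cortex. By strand discordance they were 0.0743 for Dnmt3a in discordant blood libraries at 6 h and, in the others, -0.690 for Nlrp3 in blood at 12 h, 0.0517 for Crhr1 at 6 h and -0.316 for Tet2 at 24 h in cortex, and -0.284 for Ache in hippocampus at 12 h, which the covariate gave as -0.284. Near gene ends the synaptic list of hippocampus at 6 h turned upward (adjusted p = 0.663).

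Without single libraries Dnmt3a was -0.373 to 0.187, -0.542 to 0.208 and -0.910 to 0.240 in blood, -0.0899 to 0.462 at 6 h and -0.204 to 0.392 at 24 h in cortex and -0.800 to 0.265 in hippocampus at 12 h. Crhr1 was -0.423 to 0.523, -0.478 to 0.481 and -0.471 to 0.46595 in cortex and -0.684 to 0.331 in hippocampus at 12 h, and Tet2 -0.112 to 0.691, -0.262 to 0.899 and -0.259 to 0.49284 in cortex. Nlrp3 was -0.826 to 0.878 in cortex at 24 h and -2.94 to 0.0474 in hippocampus at 12 h, and Tnf -4.70 to 0.0715 in cortex at 12 h. None of these passed the test in any of those fits.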

Other observations

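The lists of other tissues and of all leukocytes were chosen only after the result was seen, and fry was planned before the data were examined.

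Among marker genes of other tissues, those of keratinocytes and of fibroblasts and smooth muscle had the largest shares of rising tiles in LPS against saline blood at 6 h. Of 21 tiles in keratinocyte genes, which encode keratins and other proteins of the skin surface, 13 rose and 1 fell, with a median difference of 17.1 points, against a median of 1.27 over all 74713 tiles, of which 22134 rose and 8822 fell. Of 75 tiles in genes of fibroblasts and smooth muscle 31 rose and 5 fell (median 4.22), of 84 in cardiac and skeletal muscle genes 23 and 3 (1.23), of 24 in lung epithelium genes 8 and 1 (2.59), of 31 in intestinal epithelium genes 9 and 1 (1.3), and of 28 in hepatocyte genes 11 and 3 (1.22). Tiles in endothelial and pericyte genes (22 rose and 11 fell of 63, median 2.9), kidney tubule genes (15 and 11 of 54, 0.57) and adipocyte genes (3 and 2 of 19, 3.47) had 33.3, 42.3 and 40.0% of their called tiles lower, against 28.5% over all tiles. For adipocyte genes that share came from few rises. In 36 genes of all leukocytes, 33 of them with tiles, 32 tiles rose and 37 fell of 117, or 53.6% lower among the called. The keratinocyte tiles had medians of 19.6 points at 12 h and 12.1 at 24 h, with 11 rising and 1 falling each time. Of the fibroblast and smooth muscle tiles 31 of 67 rose at 12 h and 24 of 72 at 24 h. At 24 h that share was near the 22344 of 71782 over all tiles and below the 11 of 28 in hepatocyte genes. No test compared a list with other tiles, and 2 fibroblast and smooth muscle genes stood in a list fixed before the data were examined.

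In blood and in hippocampus at 6 h a number of the fixed gene lists moved on balance one way by fry, which tests the members of a list alone and sets them against no other genes. In blood 8 lists were higher and 3 lower at 6 h, 13 and 1 at 12 h, and 8 and 1 at 24 h, of 19 each time, with neutrophil markers lower (adjusted p = 0.000339, 0.000479 and 0.00103). All 19 passed the test for change in either direction at each time. In hippocampus at 6 h 12 lists were lower and none higher, led by T cell markers (adjusted p = 0.00491), and 13 passed the test for change in either direction. At 12 h and 24 h in hippocampus no list moved one way (smallest adjusted p = 0.79 and 0.0667), while 0 and 4 passed the test for either direction (smallest adjusted p = 0.549 and 0.006). In cortex none passed either test (smallest one-way adjusted p = 0.79, 0.588 and 0.669).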
